A study of Mus musculus with 20 samples.

How the data were processed

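The series holds 20 samples of TL1 mouse cells, 8 RNA-seq, 8 ChIP-seq and 4 input libraries. RNA-seq had 2 libraries in each of 4 groups, ES and EB by wild type and knockout. H3K27me3 and H3K4me3 ChIP-seq had 1 library in each of the 4 groups. The input libraries have no column in the processed tables and were not analysed here. Columns were mapped to samples by name, and 0 columns of values were left unmapped. The ChIP columns carry codes that match those in the samples' descriptions.

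The deposited RNA table holds FPKM, fragments mapped per gene scaled to transcript length and library size by the authors, with 1 column per library. The submitters' processing notes name mm10 and the tools STAR 2.6.0a, Cufflinks 2.2.1, Bowtie2, HTSeq and DESeq2, with no role or order. Per the file headers, the FPKM table has the column names that Cufflinks writes. Column totals ran from 641813 to 782026, so the deposited values were not scaled to a common total. The table holds no read counts. Loci were given with a 0-based start, to which 1 was added.

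The deposited ChIP tables hold a signal per gene that the authors' file names call RPKM on promoters. The values were tested against that name. In 17759 genes (86.8%) with a locus in the RNA table, H3K27me3 values rose with locus length (Spearman's rho across genes from 0.59 to 0.69, slope of log2 value on log2 length from 0.79 to 0.95). H3K4me3 values did so as well (86.9% of genes, rho from 0.43 to 0.49, slope from 0.53 to 0.61). The trend was also present in genes without expression (rho from 0.57 to 0.65 over both marks). This is how reads summed over the gene without division by its length would behave. The values were therefore not taken as per kilobase or as promoter values, and the promoter window is not stated in the labels. The design written beforehand assumed RPKM on promoters and was kept as written for its ratios, which compare the same gene between libraries. These ratios can still depend on length. With only loci under 10 kb, chosen after seeing the data, the median log2 H3K27me3 ratio of knockout over wild type EB went from -1.17 to -1.63 for pluripotency and from -0.65 to -1.18 for mesoderm genes. Apart from 324 to 1276 genes per library at a value below 1 step, nearly all values were whole multiples of a step of 0.0267, or 0.04 in the wild type EB library of H3K27me3, within 0.02 of a step. No value was negative. The number of mapped reads behind a library is not given, so the full depth is unknown. Summed over genes, the H3K27me3 values came to 4130691 steps in wild type EB and from 5372694 to 5959392 in the other H3K27me3 libraries. The median per gene was 39 steps in wild type EB and 67 in knockout EB. If a step stands for 1 read, the wild type EB library was the shallowest over these genes.

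From the FPKM table of 53560 genes and loci, 120 were left out as a second entry of the same symbol. Genes with at least 1 FPKM in at least 2 of the 8 libraries were kept, 15428 in all. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group and no other terms, with eBayes and a trend. The fit had 4 residual degrees of freedom and 7.05 after moderation. The 5 contrasts were knockout minus wild type in ES and in EB, EB minus ES in wild type and in knockout, and the difference of both knockout effects. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and calls at an adjusted p under 0.05. All adjusted p for genes are limma's.

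The 25 gene lists were fixed before the data were examined, as were the design, the alternatives in the closing section unless marked otherwise, and the rule for named genes. They cover CAF-1 subunits, other histone chaperones, pluripotency, formative and primed epiblast, neuroectoderm, mesoderm, endoderm, trophoblast, 2-cell-stage-like genes, Polycomb complexes, heterochromatin and DNA methylation machinery, germline genes, p53 targets, DNA replication, mitosis and cyclins, cell cycle inhibitors, imprinted genes, Hox genes, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, fibroblast and feeder markers, blood and endothelium markers, cardiomyocyte markers, and glycolysis and hypoxia. Lists were tested with limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 125 tests. Camera called 70 of these, and 0 of the 70 were called with an estimated correlation. Of those 125, fry called 64. fry asks whether the genes of a list move on balance one way and compares them with no other genes.

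Genes named in the text are Chaf1a, Chaf1b and Rbbp4, 19 fixed anchor genes, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 FPKM and no overlap of libraries, and up to 4 called members per list with the smallest adjusted p. Unnamed models were left out by rule, and 2, 122, 130, 78 and 76 of them were among the calls of the 5 contrasts. Models named after clones (RP23 and RP24) were not covered by that rule and stayed in. For lists without a call the member with the smallest p was named. For ChIP, the 5 largest rises and 5 largest falls among genes in the top 25 percent by mean value were added. Genes outside the rule are marked as chosen after their values were seen.

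Overlaps of calls between contrasts that share libraries were set beside the overlap of independent lists and beside 100 simulations of unchanged groups. For the ChIP tables, log2 of (value + 1) in a library over (value + 1) in another was taken per gene. The median of each list was placed among 10000 random lists of the same size matched on decile of the mean signal, and, after the length trend was seen, on length. Both ChIP tables share 20437 genes. High classes were the top 10 percent by mean value. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

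The limma steps were tested on simulated data with the wild type means of the stage and the spread of the measured genes. Only genes with a mean log2(FPKM + 1) above 2 were changed, so recovery of lower genes was not tested. Noise was drawn independently for each library. For knockout minus wild type in ES, 46 of 67 genes with a log2 change of 1, 60 of 67 with 2 and 65 of 66 with 4 were called in the right direction, and 9 unchanged genes were called. For EB these were 42, 61 and 64, with 16 unchanged genes called. Alternatives covered the pseudocount, the filter, the scaling, the trend, the libraries in the fit, a replicate block, each library left out, and the classes and scaling of the ChIP values.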

Results

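The series measured gene expression and 2 histone marks in TL1 mouse embryonic stem (ES) cells and in embryoid bodies (EB), the aggregates that form when the cells differentiate without LIF. Wild type cells were compared with cells depleted by CRISPR/Cas9 of p150, the large subunit of the histone chaperone CAF-1, which is encoded by Chaf1a. RNA-seq covered 4 groups of 2 libraries each (ES wild type, ES knockout, EB wild type and EB knockout). ChIP-seq of H3K27me3, a mark of Polycomb repression, and of H3K4me3, a mark of active promoters, had 1 library per mark, stage and genotype. The RNA files give FPKM, whose totals ran from 641813 to 782026 per library, and no read counts, so the sequencing depth is unknown. The labels do not say whether both RNA replicates of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

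Chaf1a (ENSMUSG00000002835.8, mm10 chromosome 17, 56040416 to 56068026) had similar FPKM in knockout and wild type libraries. Its values were 49.5 and 43.0 in wild type ES, 48.1 and 38.0 in knockout ES, 31.7 and 32.1 in wild type EB, and 31.6 and 35.0 in knockout EB. The log2 difference was -0.11 ± 0.14 (SE, limma, adjusted p = 0.829) in ES and 0.06 ± 0.14 (adjusted p = 0.756) in EB. Gene-level FPKM cannot see a small CRISPR lesion, so these values check nothing about the genotype, which rests on the labels.

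**Figure D1:**
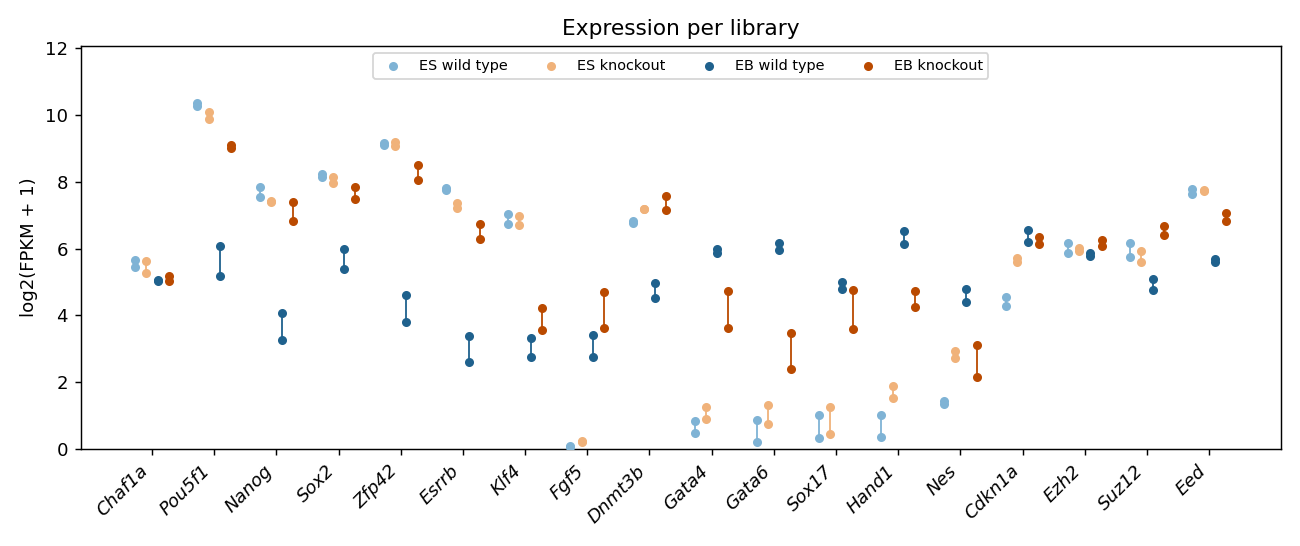
FPKM on a log2(FPKM + 1) axis for Chaf1a and 17 other genes fixed in advance, with 1 point per library and a line joining both libraries of a group. Pou5f1, Nanog and Zfp42 sat far lower in wild type EB than in the other 3 groups.

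The comparison of EB with ES in wild type cells shows the course of differentiation against which the knockout can be read. The genes that keep ES cells pluripotent fell together, while most tested genes of mesoderm, endoderm, blood and heart muscle rose. Pou5f1, the central pluripotency factor (ENSMUSG00000024406.16, chromosome 17, 35506018 to 35510772), went from 1266 ± 45.4 FPKM (SD, n = 2) in ES to 50.6 ± 21.6 in EB, a log2 change of -4.68 ± 0.26 (SE). The log2 change was -4.02 for Nanog, -2.48 for Sox2, -4.78 for Esrrb and -4.91 for Zfp42. All 42 tested members of the pluripotency list were called lower, with a median of -3.80 (camera adjusted p = 1.77e-20; adjusted p = 0.481 with an estimated correlation). The counts adjusted over the list alone were the same.

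Many germ layer and tissue genes rose in wild type EB. Igf2, a fetal growth factor and imprinted gene, rose by 9.60 ± 0.27 on the log2 scale, from 2.86 ± 0.905 to 2953 ± 42.0 FPKM. Among mesoderm genes, 18 of 23 rose and 2 fell, with Hand1 at 5.63 and T, the primitive streak factor, at 3.22. Among endoderm genes, 22 of 26 rose (23 adjusted over the list alone) and 0 fell, with Gata4 at 5.28 and Gata6 at 5.51. All 21 tested Hox genes, which pattern the body axis, rose, with a median of 1.75 and Hoxb4 at 2.85. The list holds 39 Hox genes, and the others did not pass the FPKM filter. A gene expressed in wild type EB alone passes it, which favours rises here and lower values in knockout EB. All 19 blood and endothelium markers and all 12 cardiomyocyte markers rose, with Hba-x, an embryonic globin, at 8.24 and Tnnt2, a troponin of heart muscle, at 8.54. Camera called these 5 lists, and their adjusted p with an estimated correlation was 0.572 for mesoderm and 0.481 for each of the others. Of 12 neuroectoderm genes 7 rose, with Nes at 3.18 and Irx3 at 4.93, and 2 fell (camera adjusted p = 0.184). Fibroblast and feeder markers also rose in 14 of 15 cases, with Col1a2 at 5.69. DNA replication genes fell in 19 of 26 cases (20 adjusted over the list alone), with Mcm5 at -1.58, and 2 rose. The cell cycle inhibitor Cdkn1c rose by 4.57. Chaf1b, the CAF-1 p60 subunit, was at -0.77 ± 0.12. Chaf1a itself was at -0.52 ± 0.14 (adjusted p = 0.0150), a call that ended without ES wild type replicate 1 (adjusted p = 0.0876), EB wild type replicate 1 (0.0649) or EB wild type replicate 2 (0.0575).

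In all, limma called 5576 of 15428 genes higher and 3824 lower in wild type EB, 3613 and 1892 of them by 2-fold or more. Quantile normalization moved the median of all genes from 0.12 to -0.11 and the share of higher calls from 59.3% to 46.3%, so the balance of higher against lower calls depends on the scaling.

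The comparison of knockout with wild type EB asked what CAF-1 loss changed once differentiation had begun. Knockout EB kept high levels of pluripotency genes and had low levels of many genes of differentiated tissues. Pou5f1 stood at 528 ± 27.5 FPKM (SD, n = 2) against 50.6 ± 21.6 in wild type EB, a log2 difference of 3.42 ± 0.26 (SE, adjusted p = 0.000323). Nanog was higher by 3.44 ± 0.29, Esrrb by 3.51 ± 0.25, Zfp42 by 4.07 ± 0.26 and Sox2 by 1.96 ± 0.20. Actc1, the actin of heart muscle (ENSMUSG00000068614.7, chromosome 2, 114047282 to 114053548), was lower by 6.74 ± 1.29 on the log2 scale. Its knockout values were unequal, at 1.15 and 58.2 FPKM, against 1415 and 1021 in wild type EB.

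Of 42 pluripotency genes 38 rose and 1 fell in knockout EB, with a median of 2.86 (camera adjusted p = 1.15e-18; adjusted p = 0.481 with an estimated correlation). Examples are Tcl1 at 4.30, L1td1 at 3.86, Gdf3 at 3.10 and Dppa5a at 4.53. Klf4, a factor of the naive state, was higher by 0.86 ± 0.27 (adjusted p = 0.0369), a call that ended without EB knockout replicate 1 (adjusted p = 0.204), EB wild type replicate 1 (0.194), ES knockout replicate 1 (0.050) or either wild type ES library (0.0526 and 0.0523). Of 20 formative and primed epiblast genes 11 rose and 4 fell, with a median of 1.01 (camera adjusted p = 0.0197; adjusted p = 0.561 with an estimated correlation). The de novo DNA methyltransferase Dnmt3b was higher by 2.62. Fgf5, a primed epiblast marker, was higher by 1.08 ± 0.37 (adjusted p = 0.0499), but its adjusted p was 0.239 without EB wild type replicate 1, 0.203 without EB knockout replicate 2, 0.0623 without EB wild type replicate 2 and from 0.0713 to 0.0746 without any 1 of the ES libraries. Of 23 germline genes 16 rose and 1 fell, with Tuba3a at 4.61, Xlr3a at 4.51, Tex19.1 at 3.35 and the meiotic gene Sycp3 at 2.37 (camera adjusted p = 8.02e-06; adjusted p = 0.481 with an estimated correlation).

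Most tested mesoderm, neuroectoderm and Hox genes were lower in knockout EB. The FPKM filter keeps genes expressed in wild type EB alone, which favours such falls. Of 23 mesoderm genes 14 fell and 4 rose, with a median of -1.84 (camera adjusted p = 0.0308; adjusted p = 0.703 with an estimated correlation). The heart factors Nkx2-5 and Tbx5 were at -4.48 and -3.20, Hand1 at -1.84 and T at -1.21. Among the 4 that rose were Eomes at 1.58, Mixl1 at 1.11 and Wnt3 at 1.05, chosen after their values were seen. The list therefore did not move as a whole. Of 12 neuroectoderm genes 8 fell and 0 rose, with Irx3 at -2.93, Lhx2 at -2.83 and Nes at -1.94 (camera adjusted p = 0.00549; adjusted p = 0.481 with an estimated correlation). Pax6, a neural factor, was at -1.51 ± 0.34 (adjusted p = 0.0101), a call that ended without EB knockout replicate 1 (adjusted p = 0.0570) or EB wild type replicate 1 (0.0557). Of 26 endoderm genes 10 fell and 3 rose, and the list was not called (camera adjusted p = 0.316). Its members Gata6, at -3.12, and Afp, at -3.49, fell, while Sox17 was at -0.71 ± 0.44 (adjusted p = 0.229). Of 21 Hox genes 20 fell (21 adjusted over the list alone), with Hoxb2 at -2.08 and Hoxc8 at -1.79 (camera adjusted p = 3.04e-07; adjusted p = 0.481 with an estimated correlation). Of 26 imprinted genes 17 fell (19 adjusted over the list alone) and 1 rose, with Plagl1 at -3.83, Igf2 at -2.49 and Gnas at -2.22 (camera adjusted p = 5.68e-05; adjusted p = 0.481 with an estimated correlation).

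Markers of other cell types moved with these groups. Of 19 blood and endothelium markers 15 fell and 0 rose, with the globins Hbb-y at -6.12 ± 0.65, Hba-x at -5.84 and Hba-a1 at -5.60. Of 12 cardiomyocyte markers 11 fell, with Tnni1 at -4.29 and Myl4 at -4.73. Of 15 fibroblast and feeder markers 13 fell and 1 rose, with Postn at -5.08 and Lum at -4.68. Camera called all 3 lists, each with an adjusted p of 0.481 with an estimated correlation. The median log2 differences were -1.88, -4.64 and -3.02.

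Genes of growth and chromatin were also called. DNA replication genes rose in 20 of 26 cases, with Orc1 at 1.54, Rfc5 at 1.35 and Mcm10 at 1.24, and 0 fell. Mitosis and cyclin genes rose in 15 of 21 cases (16 adjusted over the list alone) and 1 fell, with Ccne1 at 1.62. Camera called both lists, with adjusted p of 7.67e-07 and 0.000339, and with an estimated correlation the adjusted p were 0.481 and 0.419. Ribosomal protein genes rose in 66 of 81 cases (71 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 6.52e-15; adjusted p = 0.489 with an estimated correlation). They took 27.5% and 25.3% of all FPKM in the knockout EB libraries against 20.9% and 17.9% in wild type EB. From ES to EB, 56 of the 81 ribosomal protein genes rose in knockout and 2 fell. The list median was 0.63 (camera adjusted p = 1.72e-11; adjusted p = 0.535 with an estimated correlation). In wild type the median from ES to EB was -0.078 (camera adjusted p = 0.0608). The Polycomb list went both ways, with 13 of 31 genes higher (14 adjusted over the list alone) and 8 lower (camera adjusted p = 0.229). Suz12, at 1.60, Eed, at 1.32, and Jarid2, at 1.37, all parts of the H3K27 methyltransferase complex, rose, while the catalytic subunit Ezh2 was at 0.34 ± 0.12 (adjusted p = 0.0609). Chaf1b was higher by 0.56 ± 0.12 (adjusted p = 0.00867), a call that ended without EB knockout replicate 1 (adjusted p = 0.0603) or EB wild type replicate 2 (0.0502). The p53 target Cdkn1a was at -0.11 ± 0.16 (adjusted p = 0.596).

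Several of the other lists had called genes in both directions. Of 17 heterochromatin and DNA methylation genes 7 rose (8 adjusted over the list alone) and 6 fell, with Zfp57 at 1.95 and Hells at 1.55 (camera adjusted p = 0.226). Of 15 trophoblast genes 6 rose (7 adjusted over the list alone) and 3 fell, with Tfap2c at 1.93 and Fgfr2 at -1.52 (camera adjusted p = 0.255). Of 24 p53 targets 8 rose (10 adjusted over the list alone) and 2 fell, with Pmaip1 at 2.91 and Fas at -0.90 (camera adjusted p = 0.0436; adjusted p = 0.588 with an estimated correlation). Of 20 other histone chaperones 8 rose and 2 fell, with Set at 1.11 (camera adjusted p = 0.0401; adjusted p = 0.481 with an estimated correlation). Of 18 glycolysis and hypoxia genes 6 rose and 1 fell, with Pfkp at 2.32 (camera adjusted p = 0.00279; adjusted p = 0.588 with an estimated correlation). Of 12 cell cycle inhibitors 4 fell (3 adjusted over the list alone) and 1 rose, with Cdkn1c at -2.50 and Gadd45a at 1.40 (camera adjusted p = 0.569). Of 43 replication-dependent histones 10 fell (8 adjusted over the list alone) and 0 rose, with Hist1h1c at -1.85 (camera adjusted p = 0.244). Among all 15428 tested genes 3992 were called lower, a larger share than among these histones. None of the 13 mitochondrially encoded genes and none of the 5 genes of the 2-cell-stage list was called. Of the 3 CAF-1 subunits 2 rose, Chaf1b and Rbbp4, the latter at 0.30 ± 0.10 (adjusted p = 0.0498), and its adjusted p was 0.201 without EB wild type replicate 2.

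limma called 3082 genes higher and 3992 lower in knockout EB, 1279 and 2041 of them by 2-fold or more. Without EB knockout replicate 1 the counts were 1826 and 2464, and without EB wild type replicate 2 the lower calls numbered 2585. Lower calls did not outnumber higher ones under every setting, with 3601 higher and 3500 lower after quantile normalization (50.7% higher against 43.6%) and 2397 and 2321 among genes with a mean of at least 5 FPKM. The largest falls by the rule for named genes also held gene models with a very short locus, mt-Ts1 and Hbb-bh0, which were listed at 0 in both knockout EB libraries and at 3986 and 4085 FPKM, and at 1536 and 810 FPKM, in wild type EB.

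**Figure D2:**
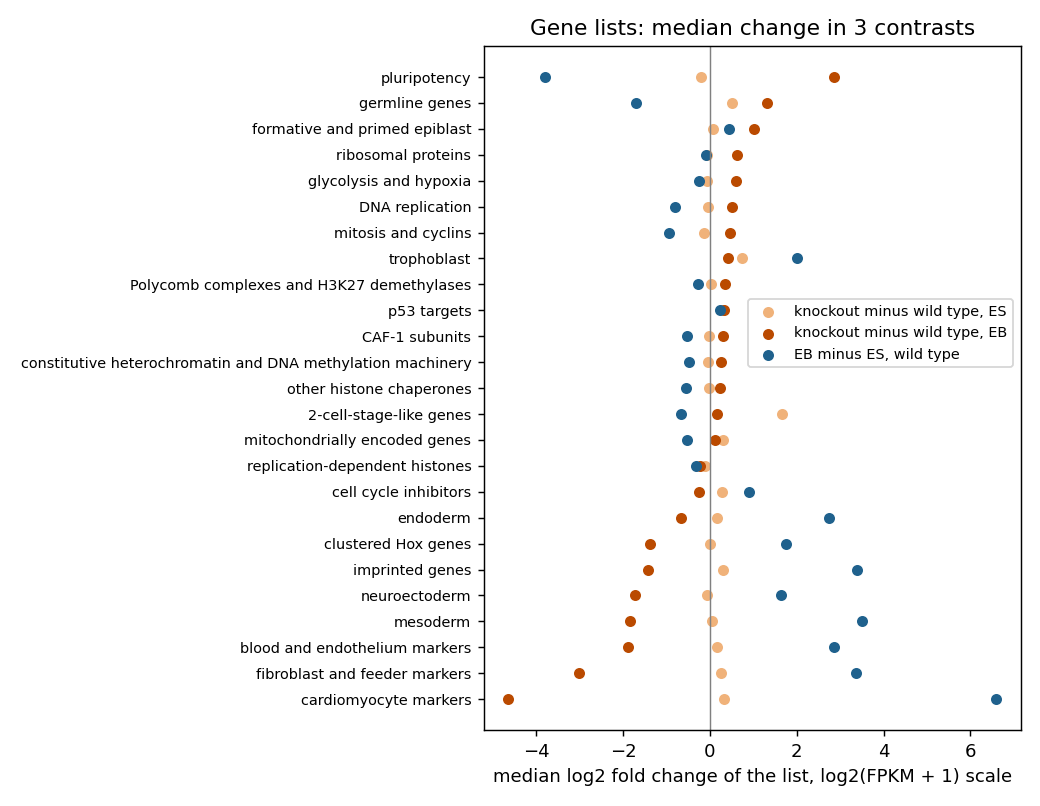
Median log2 fold change of each of the 25 gene lists in 3 contrasts, 1 point per list and contrast. The pluripotency list lay at -3.80 for wild type EB minus ES and at 2.86 for knockout minus wild type EB.

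In ES cells limma called few genes between knockout and wild type, and no pluripotency gene was among the calls. The largest rises were in Xlr genes, a cluster of X-linked lymphocyte-regulated genes. Xlr5a (ENSMUSG00000058328.13, chromosome X, 73107635 to 73292976) had 0.861 and 0.743 FPKM in wild type and 28.5 and 24.1 in knockout ES, a log2 difference of 3.92 ± 0.28 (SE, adjusted p = 0.00545). Xlr5c at 3.83, Xlr3c at 3.75, Xlr5b at 3.65, Xlr3b at 2.54 and Xlr3a at 2.37 were also called. These genes are near-identical copies that may share reads, so the split between them is uncertain. Thy1, a surface glycoprotein, rose by 2.75 ± 0.27, Krt18, a keratin of simple epithelia, by 2.28 ± 0.17, Igf2 by 2.46 ± 0.27 and the p53 target Cdkn1a, an inhibitor of cyclin-dependent kinases, by 1.23 ± 0.16 (adjusted p = 0.0353). The germ cell gene Tex101 rose by 2.18, Amn by 1.36 and Cldn6, a tight junction protein, by 1.00. Lower genes included Ppp2r3d at -2.64 ± 0.20, Spink1 at -2.31, Fgf17 at -1.85, Inhbb at -1.46, Ly75 at -1.40 and Itga9 at -1.33. The clone-named models RP23-211O3.5 and RP24-174D10.3 had the largest falls and were listed at 0 in both knockout ES libraries.

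By group, 0 of 42 pluripotency genes were called by limma, also when adjusted over the list alone, with Pou5f1 at -0.33 ± 0.26 (adjusted p = 0.663) and Nanog at -0.28 ± 0.29 (adjusted p = 0.759). Their median of -0.21 was called by camera (adjusted p = 0.000466; adjusted p = 0.545 with an estimated correlation). Of 23 germline genes 2 rose (4 adjusted over the list alone; camera adjusted p = 5.68e-05; adjusted p = 0.481 with an estimated correlation). Of 15 trophoblast genes 1 rose (4 adjusted over the list alone; camera adjusted p = 0.000188; adjusted p = 0.419 with an estimated correlation). The 5 tested genes of the 2-cell-stage list were the Zscan4 genes, with a median of 1.65, and 0 were called over all genes and 5 adjusted over the list alone. Their estimated correlation was 0.98, so the 5 genes varied almost together and do not count as separate results. Zscan4e was at 1.65 ± 0.40 (adjusted p = 0.137; camera adjusted p = 8.73e-05 and adjusted p = 0.481 with an estimated correlation for the list), with 0.971 and 0.266 FPKM in wild type ES and 6.68 and 2.22 in knockout ES. Of 15 fibroblast and feeder markers 1 rose, Thy1 (2 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.184). The p53 target list had a median of 0.31, with 1 of 24 called (camera adjusted p = 0.00131; adjusted p = 0.481 with an estimated correlation). Of 26 imprinted genes 1 rose (4 adjusted over the list alone; camera adjusted p = 0.00468; adjusted p = 0.535 with an estimated correlation). None of the 21 Hox, 31 Polycomb, 26 DNA replication or 81 ribosomal protein genes was called over all genes, and the medians were 0.011, 0.036, -0.032 and -0.074. With 2105 genes at an unadjusted p under 0.05, camera called the ribosomal list (adjusted p = 0.00238; adjusted p = 0.711 with an estimated correlation) and not the other 3. Camera also called the mitochondrially encoded genes higher (median 0.31; adjusted p = 0.0165; adjusted p = 0.640 with an estimated correlation) and 3 lists lower, each with 0 genes called over all genes. These were mitosis and cyclins (median -0.14; adjusted p = 0.0384; 0.481 with an estimated correlation), replication-dependent histones (-0.11; 0.0104; 0.481; 1 higher and 8 lower adjusted over the list alone) and glycolysis (-0.069; 0.0401; 0.682). The histone and glycolysis medians were 0.065 (adjusted p = 0.291) and 0.11 (0.374) without wild type replicate 2 and 0.010 (0.294) and 0.12 (0.836) without knockout replicate 1, so their direction is uncertain. The calls of these 4 lists and of the ribosomal, p53 target and imprinted lists each ended when at least 1 ES library was left out. All models of the mitochondrial genome took 2.55% and 2.51% of all FPKM in wild type ES and 2.91% and 3.36% in knockout ES. These shares include models outside the list of 13 genes, such as mt-Ts1, so they do not measure the list itself.

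limma called 65 genes higher and 12 lower in knockout ES, with 2105 at an unadjusted p under 0.05, and these counts depended on each library. Higher and lower calls numbered 13 and 7 without wild type replicate 1, 2 and 4 without wild type replicate 2, 3 and 4 without knockout replicate 1, 28 and 7 without knockout replicate 2, 7 and 5 without either wild type EB library, and 38 genes were called higher without knockout EB replicate 1 and again without replicate 2. With only the 4 ES libraries in the fit the counts were 0 and 1. Of the 23 named genes called here, 2 were called whichever library was left out, and both are the clone-named models.

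The comparison of EB with ES in knockout cells shows how far these cells had moved. Most tested endoderm and mesoderm genes rose in knockout cells, while most neuroectoderm genes were not called. Their pluripotency genes fell by less, with a median of -0.85 against -3.80 in wild type. Pou5f1 was at -0.93 ± 0.26 (adjusted p = 0.0341), Nanog at -0.30 ± 0.29 (adjusted p = 0.472) and Sox2 at -0.40 ± 0.20 (adjusted p = 0.182), whereas Klf4 was at -2.92 ± 0.27 and Socs3, a target of LIF signalling, at -3.17. The Pou5f1 call ended without EB knockout replicate 1 (adjusted p = 0.0985) or 2 (0.135), ES knockout replicate 1 (0.137) or 2 (0.0808), or ES wild type replicate 1 (0.0559) or 2 (0.0558). Fgf5 rose by 3.94 ± 0.37 and Otx2, another factor of the primed epiblast, by 2.63. Besides the calls marked in the text, calls of some other named genes in this and the other contrasts also ended when a library was left out.

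Of 42 pluripotency genes 22 fell (27 adjusted over the list alone) and 1 rose (camera adjusted p = 1.67e-08; adjusted p = 0.481 with an estimated correlation). Of 26 endoderm genes 21 rose and 1 fell, with Ttr at 4.03, Sox17 at 3.32 and Gata4 at 3.10 (camera adjusted p = 6.70e-08; adjusted p = 0.481 with an estimated correlation). Of 23 mesoderm genes 14 rose (17 adjusted over the list alone) and 1 fell, with Fgf8 at 3.13, Hand1 at 2.78 and T at 2.25 (camera adjusted p = 8.26e-05; adjusted p = 0.550 with an estimated correlation). Only 3 of 21 Hox genes rose, among them Hoxb2 at 1.54 and Hoxb4 at 1.24 (camera adjusted p = 0.0178; adjusted p = 0.626 with an estimated correlation). Cardiomyocyte markers rose in 2 of 12 cases (camera adjusted p = 0.0924) and blood and endothelium markers in 7 of 19 (10 adjusted over the list alone; camera adjusted p = 0.00288; adjusted p = 0.504 with an estimated correlation). Of 12 neuroectoderm genes 1 rose, Irx3 at 1.84, and 1 fell. Igf2 rose by 4.65 and H19 by 3.51. limma called 2640 genes higher and 1847 lower, 1162 and 660 by 2-fold or more. The excess of higher calls depended on the scaling, with 2247 higher and 2321 lower after quantile normalization (49.2% higher against 58.8%) and 2264 and 2217 after rescaling by median of ratios. The counts were 1374 and 940 without ES knockout replicate 1, 1657 higher without ES knockout replicate 2, 1003 lower without EB knockout replicate 1, 1481 and 925 without EB knockout replicate 2, and 1440 and 1029 with only the 4 knockout libraries in the fit.

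**Figure D3:**
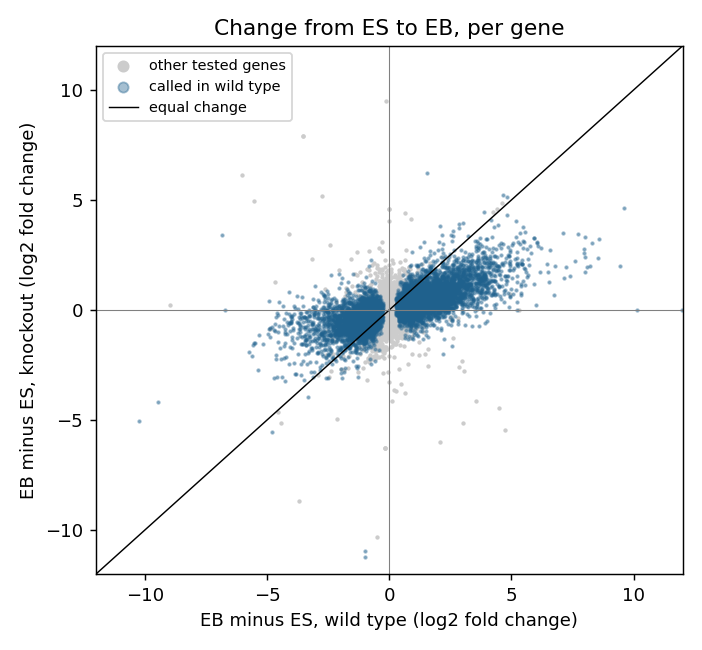
Log2 fold change from ES to EB of each tested gene in wild type (x axis) and in knockout cells (y axis), with the line of equal change. Most genes called with a change of 2-fold or more in wild type lay nearer to 0 in knockout cells, with a median ratio of 0.35 for those that rose and 0.33 for those that fell.

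Whether the genes that change in wild type differentiation changed less in knockout cells was asked directly. Across 15428 genes the changes in both genotypes, which share no library, correlated at r = 0.61 (covariance 0.67), and genes are not independent replicates. Among 3613 genes that rose 2-fold or more in wild type, 3262 moved the same way in knockout and 1597 were called, with a median ratio of knockout to wild type log2 change of 0.35 (quartiles 0.17 and 0.53). Among 1892 genes that fell 2-fold or more the median ratio was 0.33 (quartiles 0.12 and 0.55), and 829 were called. Selecting genes by their wild type change favours ratios under 1. Igf2 shows the pattern, with a log2 change of 9.60 in wild type and 4.65 in knockout cells.

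Of the 3824 genes that fell in wild type differentiation, 2284 (59.7%) were higher in knockout than in wild type EB, and of the 5576 that rose, 3430 (61.5%) were lower. Independent lists would share 764 and 1443 genes, which leaves out the shared wild type EB libraries. Simulated unchanged groups with those libraries shared 0.02 on average in each case, which leaves out all effects and does not measure how much the shared libraries add to these overlaps. Only 48 and 76 genes went the other way. The changes correlated at r = -0.79 with a covariance of -1.14, against -0.50 and -0.051 in simulated unchanged groups, and part of the excess may come from the shared libraries. Without EB knockout replicate 1 the shared counts were 1506 and 2285.

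The knockout effect differed between stages for many genes, as a test of the difference itself showed. The difference was 3.75 ± 0.36 for Pou5f1, 3.72 ± 0.41 for Nanog and 4.84 ± 0.32 for Tcl1 on the log2 scale. It was -3.62 ± 0.57 for Gata6, -3.36 ± 0.45 for Nes, -1.34 ± 0.22 for Cdkn1a and -4.95 ± 0.38 for Igf2, which was higher in knockout ES and lower in knockout EB. Of 42 pluripotency genes 36 had a higher knockout effect in EB (38 adjusted over the list alone), and of 21 Hox genes 16 had a lower one (19 adjusted over the list alone). limma called 1959 genes with a higher and 2874 with a lower effect in EB, 40.5% higher, a share that was 51.7% after quantile normalization. Without ES wild type replicate 1 the counts were 1180 and 1767, without ES wild type replicate 2 they were 1298 and 1729, without EB wild type replicate 2 they were 1258 and 1621, and without EB knockout replicate 1 they were 1127 and 1730. Across genes, the knockout effects in ES and in EB correlated at r = 0.03.

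The ChIP values asked how H3K27me3 and H3K4me3 differed with the same groups. They have no replicates, so no test was made, and percentiles among random lists describe these libraries only. The titles of the EB ChIP samples carry a digit that the RNA titles lack, and the labels do not explain it. Whether the EB of both assays were of the same age is therefore unknown. The values grew with the length of the gene, so they are called values per gene here and are compared only for the same gene between libraries. H3K27me3 on pluripotency genes was gained in wild type EB and less so in knockout EB. Pou5f1 had an H3K27me3 value of 0.133 in wild type ES and 0.133 in knockout ES, 16.6 in wild type EB and 2.46 in knockout EB, while its H3K4me3 value was 40.2, 40.3, 10.5 and 39.3. Fgf4, a growth factor of pluripotent cells, had 0.187 in wild type ES, 32.7 in wild type EB and 4.00 in knockout EB for H3K27me3.

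In wild type, the median log2 ratio of H3K27me3 in EB over ES was 1.56 for the 42 pluripotency genes, 1.82 for the 39 Hox genes, 1.78 for neuroectoderm and 0.99 for mesoderm genes. In knockout it was 0.61, 0.92, 0.77 and 0.36. Knockout EB over wild type EB gave -1.17, -1.40, -1.56 and -0.65, each below all of the 10000 random lists, and 0 of 39 Hox genes had a ratio above 0. Random lists matched on gene length put the Hox and neuroectoderm medians at percentile 0 as well. Both kinds of random list draw genes separately, while Hox genes lie in clusters. The Hox percentile and the 0 of 39 can therefore overstate the evidence. Formative and primed epiblast genes were also lower, at -1.05. Endoderm genes (-0.051) and imprinted genes (0.14) lay within their random lists. With only loci under 10 kb, chosen after seeing the data, their medians were -0.41 and 0.0003. In ES cells the knockout over wild type ratio was -0.44 for Hox genes, with 0 of 39 above 0, -0.33 for neuroectoderm genes and 0.00 for pluripotency genes. In RNA, 21 Hox and 12 neuroectoderm genes were tested, and 20 and 8 of them were lower in knockout EB and 0 higher. The ChIP medians cover 39 and 29 genes, so many genes with a ChIP ratio have no RNA result.

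For H3K4me3, knockout over wild type EB was 1.04 for pluripotency genes, -0.74 for neuroectoderm, -0.73 for Hox, -0.36 for mesoderm and -0.71 for imprinted genes. These sizes depended on the scaling, and with the same median over genes below the median they were 0.44, -1.37, -1.31, -0.94 and -1.34. Zfp42 had an H3K4me3 value of 69.3 in wild type ES, 7.55 in wild type EB and 44.3 in knockout EB. Igf2 had 5.15 in wild type ES, 72.3 in wild type EB and 23.5 in knockout EB. Xlr3a had 0.800 in wild type and 6.16 in knockout ES. Across genes, Spearman's rho between the log2 ratio of a mark and the RNA change in the same contrast was -0.26, -0.37, -0.42 and -0.40 for H3K27me3 and 0.42, 0.53, 0.57 and 0.29 for H3K4me3 (knockout over wild type in ES and in EB, EB over ES in wild type and in knockout). Genes are not independent replicates, so no p is given.

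**Figure D4:**
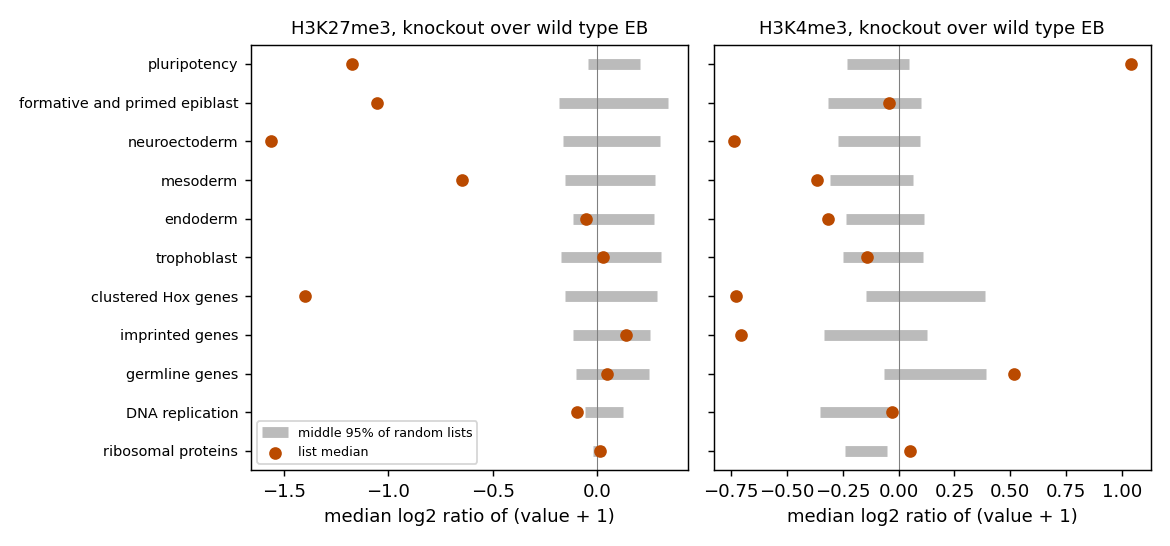
Median log2 ratio of knockout over wild type EB for H3K27me3 (left) and H3K4me3 (right) in 11 gene lists, with grey bars for the middle 95% of random lists matched on signal. Hox and neuroectoderm genes lay below their bars for both marks, at -1.40 and -1.56 for H3K27me3.

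Genes in the top 10% by H3K27me3 value, and the bivalent genes that also had H3K4me3 above its median, were mostly long genes. Their median locus was 133 kb and 163 kb, and most of these genes lay in the longest 10% (53.9% and 61.3%). Knockout over wild type EB had a median H3K27me3 ratio of 0.08 and 0.12 in these classes, but -0.56 and -0.90 when the classes were ranked by value per kb, a choice made after the length trend was seen. EB over ES in wild type gave 0.02 and -0.04 by value and 0.91 and 1.24 by value per kb. The classes by value per kb held mostly other genes, with 444 of 1776 and 211 of 1300 shared with those by value. With the classes by value unchanged and the libraries scaled to the same median over all genes, knockout over wild type EB gave -0.11 and -0.068. The direction in these classes therefore depends on the ranking and on the scaling.

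**Figure D5:**
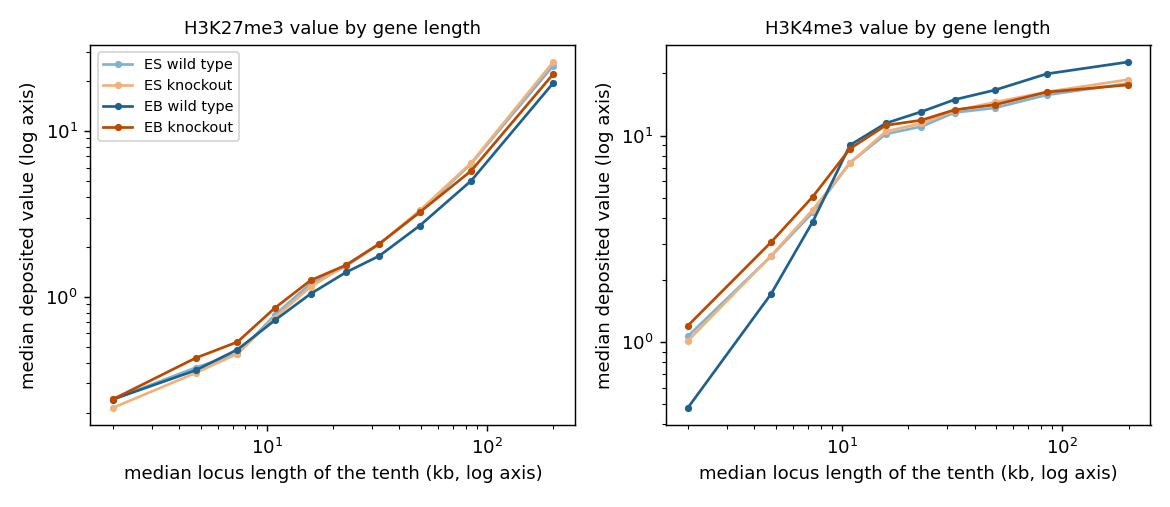
Median deposited value of genes in 10 classes of locus length, on log axes, for each library of both marks. H3K27me3 in wild type ES went from 0.24 in the shortest class to 24.7 in the longest.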

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

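Among the tests in this part, those of a mixed sample, of a mislabelled sample, of shared Xlr reads and of the Xlr level in each knockout library were chosen after the results were seen, and matching on gene length was added after the length trend was seen.

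Of the patterns weighed further below, only the first was flagged by the test described here. The results in this and the next paragraph stand out because the effect of the knockout differed between ES and EB, by a test of the difference itself. The difference is the log2 knockout effect in EB minus that in ES. It was higher in EB for 1959 genes and lower for 2874. Among anchor genes it was 3.75 for Pou5f1, 3.72 for Nanog, 2.08 for Sox2, 4.00 for Esrrb, 4.06 for Zfp42, 2.23 for Dnmt3b, 1.80 for Suz12 and 1.28 for Eed, and 0.59 for Chaf1b. It was -0.97 for T, -2.18 for Gata4, -3.62 for Gata6, -3.36 for Nes, -2.85 for Hand1 and -1.34 for Cdkn1a. The calls for T and Chaf1b were close to the threshold and ended in most fits that left out 1 library, with adjusted p up to 0.115 for T and 0.118 for Chaf1b.

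By list, the median difference was 2.86 for pluripotency, 1.03 for formative and primed epiblast, 0.91 for germline, 0.61 for DNA replication, 0.47 for mitosis, 0.71 for ribosomal protein, 0.79 for glycolysis and 0.31 for other histone chaperone genes. It was -2.54 for mesoderm, -1.80 for imprinted, -1.45 for Hox, -3.09 for fibroblast and feeder, -2.19 for blood and endothelium and -4.74 for cardiomyocyte genes. Camera called these lists with a preset correlation and none of them with an estimated one.

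The first pattern is that pluripotency genes were higher in knockout than in wild type EB, and a lower list median of 2.90 over both rescalings argues against library scaling as the whole cause. An ES library carrying a knockout EB label would differ little from knockout ES, but 29.1% of tested genes differed between them. A mixture of cells at the levels of knockout ES and of wild type EB needs 1 share of ES cells for all genes, but 12 of 40 pluripotency genes (30.0%, against a bound of 10%, with a lower counting limit of 13.0% that treats genes as independent, which genes of a list are not) lay off the level that the median share gives, with shares from 1.21% for Socs3 to 293% for Lefty2 (median 51.1%, quartiles 40.9% and 73.2%). This argues against such a mixture as the whole cause, while the 1.15% of all genes that lay 2-fold beyond both (lower limit 0.984%) did not decide it, and mixtures with cells in other states stay open. The median share was 57.3% in knockout EB library 1 and 44.9% in library 2, so these libraries differed in how near they lay to wild type EB. No biological explanation was tested, so loss of CAF-1 and a difference between the cell lines both stay open.

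Lower H3K27me3 values on Hox and neuroectoderm genes in knockout EB are the second pattern. Rescaling the libraries to a common median left the higher of both list medians at -1.58 log2. Random lists matched on gene length put the higher of both medians at percentile 0, which argues against the growth of values with length as the whole cause. These lists draw genes separately, so the percentile can overstate the evidence for the clustered Hox genes. The fall was not particular to EB, since the Hox and neuroectoderm medians of knockout over wild type ES were -0.44 and -0.33. Nor was it particular to Hox and neuroectoderm genes. In EB, medians were -1.17 for pluripotency and -1.05 for formative and primed epiblast genes, but -0.051 for endoderm and 0.027 for trophoblast genes. High and bivalent genes ranked by value per kb were at -0.56 and -0.90, but at 0.08 and 0.12 when ranked by value. A lower efficiency of the immunoprecipitation in knockout EB could still contribute and was not tested, and with 1 library per group the spread between cultures is unknown.

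Higher Xlr genes in knockout ES are the third pattern, where reads shared between near-identical copies cannot raise the sum over all copies, and the summed FPKM of the 15 Xlr genes differed by 3.53 on the log2 scale. The test planned for a single knockout library leading the group gave 0 of 6 named Xlr genes called without knockout replicate 1 and 3 without knockout replicate 2, which is the outcome written for a leading library. Calls end with fewer libraries, however, and the log2 differences of the 6 genes stayed between 2.31 and 4.12 whichever knockout library was left out. The smallest gap between the lower knockout and the higher wild type library over the named Xlr genes was 2.10 on the log2(FPKM + 1) scale. These genes were named among calls without overlap of libraries, so a gap above 0 was set in advance and decides nothing about a leading library. Summed over all 15 Xlr genes, FPKM was 202 and 159 in the knockout and 17.6 and 13.7 in the wild type ES libraries, so both knockout libraries were higher. A clonal difference between the lines may also be a cause, which was not tested.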

How the results depend on the processing

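Leaving out loci under 300 bp, ranking ChIP classes by value per kb and taking only loci under 10 kb were chosen after seeing the data. Where a library was left out, the lone library of its group was assumed to vary like the others. Except where construction shows it, the cause was not tested. ChIP values have no replicates and an unknown number of mapped reads, which limits how small a ratio can be read.

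Of the counts of called genes, called lists and genes shared between calls, 71 stayed within 1.5 times when a library was left out and 33 did not, and 112 and 18 under other settings. Leaving out 1 library gave 2 to 38 genes higher and 4 to 10 lower in knockout ES, 1826 to 3042 higher and 2464 to 3930 lower in knockout EB, 1374 to 2299 higher and 925 to 1606 lower from ES to EB in knockout, and 1127 to 1758 higher and 1621 to 2783 lower for the difference of effects. Of genes moving back in knockout EB, 1506 to 2252 fell and 2285 to 3390 rose in wild type.

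The 65 genes higher in knockout ES became 35 with a pseudocount of 0.1, 43 without a filter, 36 with a mean of at least 5 FPKM, 39 after quantile normalization, 43 with a replicate block, 0 with only the 4 ES libraries and 108 without loci under 300 bp. The 12 lower became 6 with a pseudocount of 0.1, 4 with a mean of at least 5 FPKM and 1 with only the 4 ES libraries. Of the 43 with a replicate block, 34 were among the 65. The labels give the replicate numbers no shared origin, so no pairing was assumed. Replicate differences correlated at 0.311 between both ES groups and from 0.0678 to 0.127 between other groups, and wild type ES replicate 1 correlated as closely with knockout ES replicate 1 (0.970) as with wild type replicate 2 (0.970). Requiring a mean of at least 5 FPKM, which tests fewer genes, gave 2321 lower in knockout EB, 3324 higher in wild type EB, 1673 with a lower effect, 1907 rising in wild type and lower in knockout EB, and a median of 0.050 for germline genes from ES to EB in knockout. With only the 4 knockout libraries, ES to EB gave 1440 higher and 1029 lower. A change of at least 2-fold gave 906 and 1813 genes moving back. In knockout ES the medians of replication-dependent histones and glycolysis genes became 0.065 and 0.11 without wild type replicate 2 and 0.010 and 0.12 without knockout replicate 1, in ranges from -0.30 to 0.065 and from -0.32 to 0.12 over all omissions.

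Of the ChIP medians and correlations with RNA, 616 were labelled the same, 184 moved and 32 reversed. A median was the same if it stayed in the interval of medians of genes redrawn from its list or class. The correlations were judged by the size of their change. A change of sign was counted for classes, and for lists only where the median had lain outside its random lists, so other lists changed sign uncounted. Medians of high and bivalent genes depended on the scaling, since a common factor shifts every ratio. With the same median over all genes, H3K27me3 ratios were 0.11 (high) for knockout over wild type ES, -0.11 (high) and -0.068 (bivalent) for knockout over wild type EB, 0.10 (high) and 0.046 (bivalent) for EB over ES in wild type, -0.078 (high) and -0.084 (bivalent) for EB over ES in knockout. With the same median over all genes, H3K4me3 ratios were -0.10 (high) and -0.0060 (bivalent) for knockout over wild type ES, 0.11 (high), -0.097 (bivalent), 0.092 (DNA replication) for knockout over wild type EB, -0.33 (high), 0.015 (bivalent), -0.26 (ribosomal proteins) for EB over ES in wild type, -0.083 (high) and -0.036 (bivalent) for EB over ES in knockout. With the same median over genes below the median, H3K27me3 ratios were 0.17 (high) and 0.19 (bivalent) for knockout over wild type ES, -0.12 (high) and -0.076 (bivalent) for knockout over wild type EB, 0.060 (high) and 0.0071 (bivalent) for EB over ES in wild type, -0.19 (high) and -0.19 (bivalent) for EB over ES in knockout. With the same median over genes below the median, H3K4me3 ratios were -0.66 (high), -0.85 (bivalent), -0.58 (ribosomal proteins) for knockout over wild type EB, 0.72 (high), 1.04 (bivalent), 0.49 (heterochromatin), 0.60 (DNA replication) for EB over ES in wild type, 0.14 (high), 0.18 (bivalent), 0.016 (ribosomal proteins) for EB over ES in knockout. With classes of the top 20 percent, H3K27me3 ratios were 0.035 (high) and 0.059 (bivalent) for knockout over wild type ES, 0.066 (high) and 0.027 (bivalent) for EB over ES in wild type, 0.10 (high) and 0.082 (bivalent) for EB over ES in knockout. With classes of the top 20 percent, H3K4me3 ratios were -0.00049 (high) for knockout over wild type ES, -0.12 (high) for knockout over wild type EB, 0.10 (high) for EB over ES in wild type, 0.092 (bivalent) for EB over ES in knockout. Ranked by value per kb, H3K27me3 ratios were -0.21 (high) and -0.30 (bivalent) for knockout over wild type ES, -0.56 (high) and -0.90 (bivalent) for knockout over wild type EB, 0.91 (high) and 1.24 (bivalent) for EB over ES in wild type, 0.57 (high) and 0.66 (bivalent) for EB over ES in knockout. Ranked by value per kb, H3K4me3 ratios were 0.089 (high) and 0.099 (bivalent) for knockout over wild type ES, -0.21 (high) and -0.16 (bivalent) for knockout over wild type EB, 0.46 (high) and 0.55 (bivalent) for EB over ES in wild type, 0.20 (high) and 0.33 (bivalent) for EB over ES in knockout. With only loci under 10 kb, H3K27me3 ratios were 0.017 (DNA replication) for knockout over wild type EB. With only loci under 10 kb, H3K4me3 ratios were 0.076 (DNA replication) for EB over ES in wild type.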

Other observations

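The genes in this part were chosen after their values were seen. In knockout EB, 122 genes were called 2-fold or more above both knockout ES and wild type EB, and 56 below both. These counts include unnamed, clone-named and pseudogene models, and some models had equal values, such as Gm22317 and Gm25679. Above both were Spink1, a trypsin inhibitor, by 6.22 and 2.37 on the log2 scale, Fabp3, a fatty acid binding protein, by 2.28 and 2.97, Eomes, a mesendoderm factor, by 2.86 and 1.58, and Myb by 2.29 and 2.43. Below both was Tenm4 at -2.67 and -2.25, and Gli2, an effector of hedgehog signalling, at -1.90 and -1.62.

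Csmd1, among the longest genes, had H3K27me3 values of 265.6, 259.2, 169.7 and 163.5 in ES wild type, ES knockout, EB wild type and EB knockout.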
